A study of Mus musculus with 6 samples.

How the data were processed

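RNA sequencing was available for 6 libraries of mouse CBir1 T-cell receptor transgenic CD4 T cells, with 1 library per condition. Per the labels, 5 libraries came from donor cells sorted from the spleens of recipient mice, and the sixth was a naive CD4 control. Whether a library came from 1 mouse or from pooled mice, the sex of the mice, the number of sorted cells and the sequencing batches were not given in the sources used here. The groups were taken from the submitters' treatment labels. Libraries were prepared with an ultra-low-input protocol, per the submitters' extraction notes.

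The deposited files hold raw read counts per gene over annotated exons, without normalization, as the whole numbers and the table layout in the files show. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2, with genome build GRCm38. The strand setting, the annotation release and the treatment of reads with several alignments were not given in the sources used here. Each file lists 49315 Ensembl gene identifiers with exon coordinates on GRCm38. Gene symbols came from GENCODE release M21, which holds 48970 of the identifiers. The other 345 kept their identifiers. Coordinates in the text are the outer exon bounds in the deposited files, of which 91.4% match GENCODE.

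Total counts per library were 60622310 for No treatment, 57289670 for MEP1+CMC, 44374250 for MEP1+Metformin, 32321936 for MEP1+Rapamycin, 50177994 for MEP1+Metformin+Rapamycin and 26139000 for the naive control. Counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 0.949, 1.02, 1.14, 1.15, 1.11 and 0.711 in the same order. Genes were kept when at least 1 library had at least 2 CPM (counts scaled to the library total) and at least 10 counts, which left 12838 genes. A set of 5 loci that resemble ribosomal RNA (Lars2, Gm23935, Gm26917, Gm42418 and Gm15564) took 15.4% of the counts of the naive library and 1.00% to 3.13% of the others.

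For each pair of libraries, the TMM log2 ratio was given with an exact 95% Clopper-Pearson interval of the 2 counts, computed in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. A gene passed the size rule when the ratio was at least 2-fold and the interval excluded no change. A count of 0 was replaced by a floor of 3 counts per library, and the ratio then rests on that floor. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules and no condition had a replicate. On data simulated with counting error only, the size rule recovered 98.5% to 100.0% of 200 genes set to differ by 3-fold, over the 6 main comparisons.

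There were 4 tests fitted across genes with edgeR quasi-likelihood models (glmQLFit and glmQLFTest, robust) and Benjamini-Hochberg adjustment over the 12838 genes, called at an adjusted p below 0.05. The first set the 5 transferred libraries against the naive library, with 4 residual degrees of freedom. The second set the 4 libraries given MEP1 on days 28 and 35 against No treatment, with 3. The last pair were the metformin and rapamycin terms of an additive model of those 4 libraries, with 1 residual degree of freedom, the departure from additivity. The spread in each model also holds any treatment difference between the libraries on the same side. A lone library was assumed to vary like the others, and p-values measure only the spread between these libraries. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. On simulated data, 4-fold changes in 200 genes were recovered at 49% for the transferred against naive model, 82.5% for the MEP1 model, 96.5% for metformin and 97.5% for rapamycin, and 4.46% to 6.78% of the calls were unchanged genes. Every simulated gene had the same dispersion, that of the model, and effects were additive. The rates may therefore not hold for the real libraries.

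A set of 34 gene lists was written from general knowledge: naive and quiescence, antigen-experienced and memory, Th1, Th17, Th2, Tfh, Treg, anergy and exhaustion, early TCR response, dissociation and heat stress, proliferation, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, fatty acid oxidation, cholesterol synthesis, amino acid and ATF4 response, energy stress and FOXO, autophagy and lysosome, ribosomal proteins, ribosome biogenesis and Myc, apoptosis promoting, apoptosis opposing, p53 targets, interferon response, CD4 T-cell identity, and markers of CD8 T cells, NK cells, B cells, plasma cells, macrophages with monocytes and dendritic cells, neutrophils, erythroid cells with platelets, and stroma with endothelium. They hold 594 genes, of which 37 are in more than 1 list, 593 have a symbol in the files and 540 passed the filter. Each list's median log2 ratio was ranked among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and was called outside them below percentile 2.5 or above percentile 97.5. In the models, camera was run with a preset inter-gene correlation of 0.01 and with an estimated correlation. The camera adjusted p-values printed use the preset value unless stated.

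The genes named were chosen by a rule. For each main pair of libraries it takes the 10 higher and 10 lower genes whose interval bound nearest to no change lies farthest from it, leaving out immunoglobulin and T-cell receptor segments, pseudogenes and predicted genes. It adds up to 4 members of each list that passed the size rule, or up to 2 by abundance where none did. For each model it takes the 10 higher and 10 lower genes with the smallest p among those called. The text names part of these genes, picked after their values had been seen, and some are not reported here. The comparisons, models, lists, naming rule and most alternatives were fixed before the data were examined.

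Alternatives were DESeq2 1.42.0 size factors, library totals without TMM, no filter, a stricter filter of a mean of at least 10 CPM, removal of a smooth trend on abundance or gene length (statsmodels 0.14.6, span 0.3), the DESeq2 Wald test, the legacy quasi-likelihood of edgeR, models with 1 inhibitor alone, and leaving out each library in turn. Leaving out genes of the X and Y chromosomes, and comparing the combination library with each single-inhibitor library, were added after the values of sex-linked genes had been seen. Library totals moved the median log2 ratio of all genes to 0.50 for No treatment against naive, to 0.11 for MEP1+Metformin and for the combination against MEP1+CMC, and to 0.17 for the combination against No treatment. Plots were drawn with matplotlib 3.10.9. Sequence variants, splicing and read-level data were not analysed here.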

Results

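CBir1 T-cell receptor transgenic CD4 T cells recognise a flagellin of commensal gut bacteria. The study asked how such memory cells differ after CAMCI, cell activation with concomitant metabolic checkpoint inhibition, in which the cells meet their antigen while mTOR or energy metabolism is inhibited. On day 0, CD45.1 donor cells lacking CD44 were given to CD45.2 C57BL/6 mice, which were immunised with 50 ug CBir1 flagellin and 1 ug CT on days 1 and 7. On days 28 and 35 the treated mice received 3 ug MEP1, a multi-epitope peptide of commensal antigens, followed for 5 days by the vehicle CMC, metformin, rapamycin or both. The No treatment mice received none of these. Per the protocol, all recipients were challenged with 3 ug MEP1 on day 56, and donor cells were sorted from the spleen on day 63. The count column of the No treatment library is headed as without challenge, against its label and the protocol, and the label was used. If the heading is right, differences between the treated libraries and No treatment also hold the day 56 challenge. The comparison of No treatment with the naive control would then hold no challenge.

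There were 6 libraries, 1 each for No treatment, MEP1+CMC, MEP1+Metformin, MEP1+Rapamycin, MEP1+Metformin+Rapamycin (the combination) and the naive CD4 control, with total counts from 26139000 (naive) to 60622310 (No treatment). No condition had a replicate, so differences between 2 libraries are given as TMM log2 ratios with 95% counting intervals. Each library had counts for 18888 (naive) to 30319 (MEP1+Metformin) genes. The transgenic beta chain segment Trbv13-1 held 98.8% to 99.1% of Trbv counts in all 6 libraries, with an exact 95% binomial interval of 98.8% to 98.9% in MEP1+Metformin and of 99.1% to 99.2% in MEP1+Rapamycin.

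The comparison of No treatment with the naive control asks what transfer, immunisation and challenge had left in the cells. Effector and memory genes were far higher in the transferred cells. Of 19 measured Th1 genes, 16 passed the size rule and were higher, with a list median of 4.20. They included Ifng, the main Th1 cytokine (chromosome 10, 118441047 to 118445892, GRCm38; log2 ratio 8.62, interval 7.08 to 10.90), the chemokine Ccl4 (7.49) and the homing receptor Cxcr3 (6.96). Of 26 antigen-experienced and memory genes, 19 were higher, among them Ccl5 (6.15) and S100a4 (6.72). The Tfh list had 10 of 15 genes higher with a median of 2.02, among them Cxcr5, the receptor that guides cells to follicles (4.31), and Angptl2 (8.32). The Th17 list had 10 of 11 higher, among them Maf (7.00). Inhibitory and recently triggered genes followed the same direction, with 15 of 21 anergy and exhaustion genes higher and 1 lower (Tigit 6.11, Ctla4 5.04, Ndrg1 -4.06) and 15 of 19 early TCR response genes higher and 1 lower. Of 15 Treg genes, 7 were higher and 2 lower, led by Il10 (0 counts in naive, 6.24 with the floor of 3 counts). The list median of 0.21 lay inside the matched random lists and was 3.19 with the stricter filter.

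Genes of resting cells were lower. Of 16 naive and quiescence genes, 9 were lower, including Igfbp4 (-5.50, interval -5.55 to -5.45) and the gut homing receptor Ccr9 (-4.23). Ribosomal protein genes were lower in 36 of 36 with a median of -0.84, and 11 of them passed the size rule, such as Rps20 (-1.43). Ribosome biogenesis genes had a median of -0.44 (-0.03 with library totals), with Myc at -1.57. Interferon response genes had 8 of 30 lower, including Oas2 (-3.20), with a list median of -0.36 that was 0.06 with library totals. Energy stress and FOXO genes had a median of -0.37, which was 0.05 with library totals, with the mTOR inhibitor gene Ddit4 at -3.26. Amino acid and ATF4 genes had 1 higher and 6 lower, with a median of -0.17 that lay inside the matched random lists and was 0.24 with library totals. Proliferation genes had 11 of 21 higher, including Mki67 (3.17), and a median of 1.47 that was 0.10 over the members left by the stricter filter.

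Transcripts of other cell types also differed. Of 17 macrophage, monocyte and dendritic-cell genes 15 were higher, led by Lyz2 (6.71), and of 10 erythroid and platelet genes 6 were higher and 1 lower. Of 14 B-cell genes 8 were lower, with Ms4a1 at -2.85. NK-cell genes had 4 of 6 higher and 1 lower, plasma-cell genes 3 of 9 higher, CD8 genes 3 higher and 3 lower of 6, and neutrophil genes 2 higher and 4 lower of 6. The CD4 T-cell identity list had 2 of 18 genes higher (Cd28 1.39 and Cd4 1.00) and 2 lower. In all, 3078 of 12838 genes passed the size rule, 2110 higher and 968 lower. With library totals the split was 3231 higher and 457 lower.

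The model of all 5 transferred libraries against the naive library (edgeR quasi-likelihood, Benjamini-Hochberg) called 1259 genes, of which 538 rose and 721 fell. With library totals 2482 rose and 190 fell, by the DESeq2 Wald test 2053 rose and 1561 fell, with legacy quasi-likelihood 1257 rose and 1030 fell, and without MEP1+CMC 437 rose and 422 fell. The costimulatory receptor Tnfrsf4 rose by 3.19 (SE 0.29, adjusted p = 0.00043), Ctla4 rose by 5.22 (SE 0.56, adjusted p = 0.0010) and the RANK ligand gene Tnfsf11 rose by 4.94 (SE 0.50, adjusted p = 0.00069), each in 5 of 5 libraries. In the naive library 5 rRNA-like loci took 15.4% of the counts, and the structural RNAs Rmrp and Rn7sk fell by 5.75 (SE 0.32) and 3.48 (SE 0.21). The actin-severing gene Gsn fell by 2.76 (SE 0.19, adjusted p = 7.1e-05), also in 5 of 5. Of 26 antigen-experienced genes 12 rose (15 when adjusted over the list alone), of 19 Th1 genes 4 rose (11 over the list alone), and of 36 ribosomal protein genes 21 fell (32 over the list alone). Camera gave the antigen-experienced list an adjusted p = 1.2e-12 and the ribosomal list an adjusted p = 1.1e-15, but with an estimated correlation these were an adjusted p = 0.32 and an adjusted p = 0.43. No list in any of the 4 tests passed with an estimated correlation. That version rests on 1 to 4 residual degrees of freedom, so most lists could hardly pass it. It therefore decides nothing about them.

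**Figure D1:**
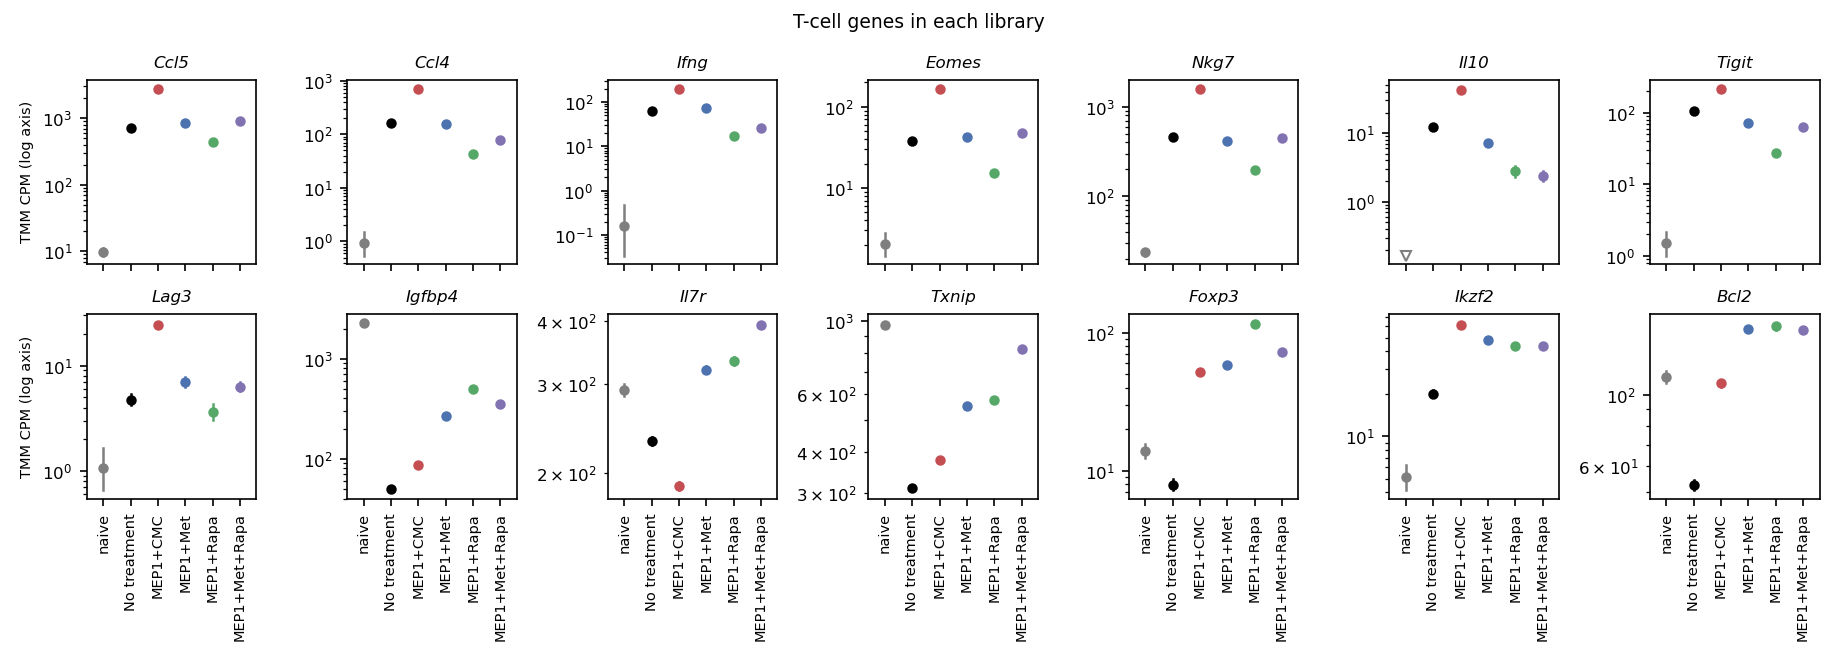
TMM CPM (log axis) of 14 T-cell genes in each of the 6 libraries, with 1 point per library, bars for the 95% counting interval and an open triangle for a count of 0. Ccl5, Ccl4, Ifng, Eomes, Nkg7, Il10, Tigit and Lag3 were highest in MEP1+CMC, while Igfbp4 was higher in MEP1+Rapamycin and the combination than in MEP1+CMC.

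The comparison of MEP1+CMC with No treatment asks what the 2 rounds of MEP1 without inhibitor had left. Th1 genes were higher after MEP1, with 9 of 19 Th1 genes higher and 1 lower and a list median of 0.52. The chemokine genes Ccl3 (2.25) and Ccl4 (2.11) and the transcription factor gene Eomes (2.13) were among them. The NK-cell list had 2 higher, including the perforin gene Prf1 (2.04), and 2 lower of 6. Treg genes were higher in 8 of 15 with a median of 1.01. Foxp3, the lineage factor of regulatory T cells (chromosome X, 7579676 to 7595243), had a log2 ratio of 2.71 (interval 2.56 to 2.85), Il10 had 1.83 and Ikzf2 had 1.63. Anergy and exhaustion genes were higher in 5 of 21 and lower in 1, with Lag3 at 2.35, Pdcd1 at 1.36 and Nr4a1 at -1.02. The Tfh list had 3 of 15 higher, including the follicular factor Ascl2 (3.18) and Il21 (1.92). Early TCR response genes split, with 5 higher and 2 lower of 19 and a median of 0.09. The naive list had 1 higher and 2 lower, with a median of -0.30 inside the matched random lists.

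Some metabolic gene lists were slightly lower. Nuclear oxidative phosphorylation genes had a median of -0.32 and none of 34 passed the size rule, cholesterol synthesis genes had -0.39 with none of 22 passing, mitochondrially encoded genes had -0.41 with none of 13, and ribosomal protein genes had -0.42 with none of 36. The medians of glycolysis (-0.15), fatty acid oxidation (-0.15) and amino acid and ATF4 genes (-0.01, which was 0.01 with DESeq2 size factors and 0.09 with library totals) lay inside the matched random lists, and that of energy stress and FOXO genes was 0.12, above them. Among survival genes, Bcl2, which opposes apoptosis, was higher (1.05), and so was the death ligand gene Fasl (1.03). Macrophage genes were lower in 13 of 17, such as Lyz2 (-2.44) and Csf1r (-2.41), and erythroid genes were lower in 8 of 10, such as Hba-a1 (-2.25). The CD4 T-cell identity list had no gene passing and a median of -0.05 (percentile 98 among the matched random lists), which was 0.06 with library totals. Xist was higher in MEP1+CMC (3.44), and the Y-linked Ddx3y (-6.87), Eif2s3y (-6.80) and Uty (-6.29) were lower. In all, 1474 genes passed, 996 higher and 478 lower.

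The model of the 4 MEP1 libraries against No treatment called 244 genes, of which 77 rose and 167 fell (edgeR quasi-likelihood, Benjamini-Hochberg). By the DESeq2 Wald test of the same design 724 rose and 305 fell. Foxp3 rose by 3.23 (SE 0.51, adjusted p = 0.025), the macrophage growth factor gene Csf1 rose by 2.14 (SE 0.31, adjusted p = 0.012) and Ttn rose by 2.15 (SE 0.29, adjusted p = 0.0079), each in 4 of 4 libraries. The complement gene C1qa fell by 2.32 (SE 0.19, adjusted p = 0.00094), Sirpa fell by 2.27 (SE 0.20) and Apoe fell by 2.75 (SE 0.26), in 4 of 4. Of 15 Treg genes 3 rose (5 when adjusted over the list alone), and camera gave an adjusted p = 5.9e-06, against an adjusted p = 0.38 with an estimated correlation. Of 17 macrophage genes 11 fell (15 over the list alone), with a camera adjusted p = 1.4e-35 and an adjusted p = 0.068 with an estimated correlation. Of the 244 genes, 21 were immunoglobulin segments and 6 were T-cell receptor segments.

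The comparisons of each inhibitor library with MEP1+CMC ask what metformin and rapamycin added to the peptide. All 3 use the same MEP1+CMC library, from which part of any likeness between them may come. MEP1+CMC also differed from all 3 in sex-linked genes, with a TMM CPM of Xist of 262 against 0.218 to 0.486. For every gene and list in these comparisons, the inhibitor and any effect of sex therefore cannot be told apart. Metformin, which inhibits mitochondrial complex I and activates AMPK, went with lower effector genes in this comparison. Of 19 Th1 genes 9 were lower and 1 higher, with a median of -0.82, led by Ccl4 (-2.21), Ccl3 (-2.21), Eomes (-1.97) and the granule gene Nkg7 (-1.93). Anergy and exhaustion genes were lower in 5 of 21, including Lag3 (-1.80), Tigit (-1.59) and the ectonucleotidase gene Entpd1 (-1.34). Early TCR response genes were lower in 4 of 19, including Ier3 (-2.08). Against No treatment, MEP1+Metformin had a Th1 median of 0.01 with none of 19 passing. Its early TCR response median there was -0.09, and both lay inside the matched random lists. The Th1 median of MEP1+Rapamycin against No treatment was -1.22, below them. The anti-inflammatory cytokine gene Il10 was lower (-2.60, interval -2.76 to -2.44), while the Treg list as a whole had 1 higher and 3 lower genes and a median of -0.09, which was 0.06 with library totals. Resting genes were higher, with all 16 naive and quiescence genes above 0, a median of 0.41 and Igfbp4 (1.62) and Dapl1 (1.05) passing. Memory genes split, with Ly6c2 higher (2.79), Ccl5 (-1.71) and Ccr2 (-1.43) lower, a median of -0.13 and a mean of 0.07.

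Some genes of the respiratory chain were lower with metformin. Mitochondrially encoded genes were below 0 in 13 of 13, with a median of -0.44, and mt-Nd4l (-1.42) and mt-Nd3 (-1.19), both complex I subunits, were the 2 that passed the size rule. Nuclear oxidative phosphorylation genes had a median of -0.31, with 33 of 34 below 0 and none passing. Glycolysis genes had a median of -0.17 and fatty acid oxidation genes a median of -0.06 (0.09 with library totals), with none of 21 and none of 19 passing. Cholesterol synthesis genes had a median of 0.15 and proliferation genes a median of 0.05 (-0.10 with the stricter filter), with none passing. Ddit4, induced by energy stress, was higher (1.01), and the energy stress list had a median of 0.18, above the matched random lists. Ribosome biogenesis genes had 0.17. The pro-apoptotic list had 2 of 19 lower, including Fasl (-1.02), and the anti-apoptotic list had none of 11 passing. Interferon genes had a median of -0.31, with Isg15 (-1.10) lower and Oas2 (1.44) higher, and the only measured stromal and endothelial gene was Pecam1 (0.53). Markers of other cell types were lower as well, with CD8 markers lower in 3 of 6 (median -1.11), NK-cell markers in 2 of 6 (-0.49) and B-cell markers in 5 of 14 (-0.77). Erythroid genes were lower in 7 of 10, plasma-cell genes in 6 of 9, and neutrophil genes had 1 higher and 4 lower of 6. Among macrophage genes Lyz2 was lower (-1.20). TMM CPM of C1qa was 17.1 against 21.6 in MEP1+CMC, while that of Csf1r was 50.5 against 40.1. Kdm5d, a Y-linked gene with 0 counts in MEP1+CMC, was 697-fold higher with the floor of 3 counts (interval from 566-fold). In all, 723 genes passed, 341 higher and 382 lower. The balance depended on the settings, with 502 higher and 301 lower with library totals, 411 and 321 with the trend on gene length removed, 2950 and 1490 without a filter and 33 and 84 with the stricter filter.

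Rapamycin, an inhibitor of mTOR complex 1, went with lower effector, follicular and checkpoint genes. Of 19 Th1 genes 13 were lower and 1 higher, with a median of -1.40. Ccl4 (chromosome 11, 83662584 to 83664683) had a log2 ratio of -4.08, Ifng -3.51 and Eomes -3.42. Of 21 anergy and exhaustion genes 12 were lower and none higher, including Havcr2 (-4.36), Tigit (-2.98) and Lag3 (-2.74). The Tfh list had 8 of 15 lower with a median of -1.26, including Cxcr5 (-2.07), Bcl6 (-1.26) and Angptl2 (-2.06). The early TCR response list had 9 of 19 lower, including the nuclear receptor gene Nr4a2 (-2.04). Other lower genes were Esm1 (-5.65), the G-protein regulator Rgs16 (-4.89) and Adgrg1 (-4.83). Among apoptosis genes, Fasl (-1.72), Pmaip1 (-1.43) and the survival gene Bcl2a1d (-1.49) were lower, and p53 targets had a median of -0.52.

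Some regulatory and resting genes were higher with rapamycin and others lower. Foxp3 was higher (1.15, interval 1.08 to 1.22), as was the Treg receptor gene Gpr83 (1.15), whereas Il10 (-3.96) was lower. The Treg list had 3 higher and 2 lower of 15, with a median of 0.49 and a mean of -0.04. Igfbp4 (2.52) and Dapl1 (2.12) were the 2 of 16 genes that passed in the naive list, whose median was 0.66 with 14 above 0. All 36 ribosomal protein genes were above 0, with a median of 0.47 and none passing. Nuclear oxidative phosphorylation genes had a median of -0.05, which was 0.01 with DESeq2 size factors and 0.11 with library totals. Glycolysis genes had a median of -0.34, inside the matched random lists, with Aldoc (-1.58) lower. The autophagy and lysosome list had a median of -0.39 and none of 21 passing. The polyamine enzyme gene Odc1 was lower (-1.52), and Ddit4 was higher (1.55). Th2 genes had only Il1rl1 (1.88) passing. Among markers of other cell types, CD8 markers had 1 higher and 3 lower of 6 (median -1.05), NK-cell markers 1 higher and 3 lower of 6 (median -0.90, which was 0.19 with the stricter filter), including Klrb1c (-3.31), and plasma-cell markers 4 of 9 lower (-0.93). Erythroid genes were lower in 8 of 10. Lyz2 was lower (-2.02), but the macrophage list had a median of -0.01, inside the matched random lists and 0.05 with DESeq2 size factors. Xist was lower (-9.08, with 18 against 15368 counts). In all, 1410 genes passed, 661 higher and 749 lower. The balance depended on the settings, with 898 higher and 582 lower with library totals, 748 and 679 with DESeq2 size factors, 737 and 625 with the trend on gene length removed, 6114 and 1592 without a filter and 72 and 271 with the stricter filter.

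The combination went with lower effector genes as well. Of 19 Th1 genes 9 were lower and none higher, with a median of -0.98, including Ccl4 (-3.20), Ccl3 (-3.11), Ifng (-2.97) and Nkg7 (-1.84). Il10 (chromosome 1, 131019845 to 131024974) was lower, at -4.17 (interval -4.43 to -3.92). Anergy and exhaustion genes had 9 of 21 lower and 1 higher, early TCR response genes had 9 of 19 lower (Egr1 -1.84), and Tfh genes 5 of 15 lower (Cxcr5 -1.34). The p53 target Cdkn1a was lower (-2.36). The naive list had a median of 0.64, with Igfbp4 (2.04), Dapl1 (1.41) and the survival cytokine receptor Il7r (1.06) higher. In the energy stress and FOXO list, Ddit4 (1.71), Txnip (1.13), Il7r and Pik3ip1 (1.01) were higher. The Treg list had a median of 0.44 and a mean of -0.03, with Itgae (2.76) higher and Tigit (-1.76) lower. The median was 0.16 with the stricter filter. The dissociation and heat stress list had a median of -0.45, below the matched random lists, with 2 of 15 lower and none higher.

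With the combination, the mitochondrially encoded list had a median of -0.46, with 3 of 13 lower, mt-Nd3 (-1.33), mt-Nd2 (-1.03) and mt-Nd4l (-1.12), and the nuclear oxidative phosphorylation list had a median of -0.23 with none of 34 passing. Ribosomal protein genes had a median of -0.02 (0.10 with library totals). NK-cell markers were lower in 3 of 6 (median -0.70) and CD8 markers in 2 of 6 (-0.36, inside the matched random lists). B-cell genes were higher in 8 of 14, including Ms4a1 (1.73), and neutrophil genes in 5 of 6, including Ltf (3.47). With the stricter filter, the B-cell median moved from 1.14 to -0.00. Igha was higher (2.89), Hba-a1 was lower (-2.86), and Eif2s3y was higher (8.41). In all, 860 genes passed, 387 higher and 473 lower. There were 507 higher and 404 lower with library totals, 2213 and 1903 without a filter and 55 and 110 with the stricter filter.

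**Figure D2:**
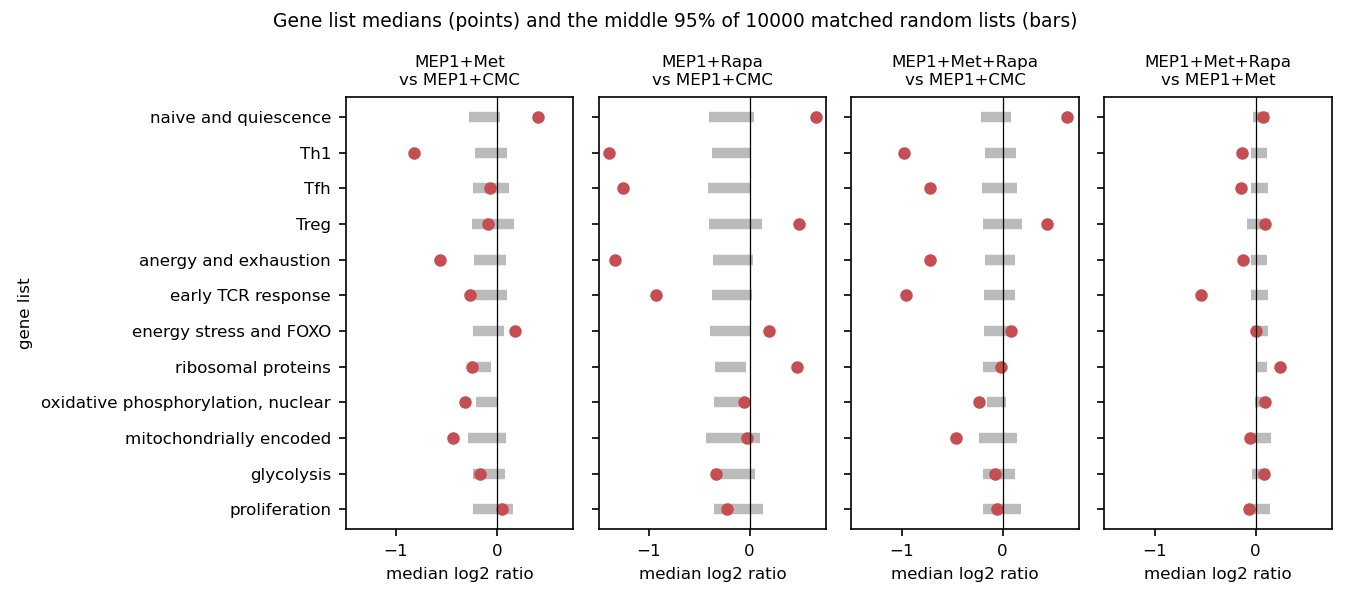
Median log2 ratio of 12 gene lists (points) beside the middle 95% of 10000 matched random lists (grey bars) in 4 comparisons. The Th1 medians were -0.82, -1.40 and -0.98 against MEP1+CMC and -0.13 for the combination against MEP1+Metformin, and the naive and quiescence medians against MEP1+CMC were 0.41, 0.66 and 0.64.

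The metformin term of the additive model over the 4 MEP1 libraries called 21 genes, of which 8 rose and 13 fell (edgeR quasi-likelihood, Benjamini-Hochberg, 1 residual degree of freedom). In models of metformin alone, 1962 rose and 640 fell without MEP1+CMC, and 15 rose and 9 fell without MEP1+Metformin. With all 4 libraries, the model of metformin alone called 0 genes by edgeR, with 855 at an unadjusted p under 0.05, and the DESeq2 Wald test of the additive model called 9, of which 1 was among the 21, and gave no adjusted p for 11947 genes. Of the 21, 8 were immunoglobulin segments and 3 T-cell receptor segments. The keratin genes Krt15 and Krt14 went opposite ways, as Krt15 rose by 2.22 (SE 0.28, adjusted p = 0.00057) and Krt14 fell by 2.60 (SE 0.33, adjusted p = 0.00057). Capn11 rose by 4.42 (SE 0.72, adjusted p = 0.0077) and the heat shock gene Hspa1b fell by 1.12 (SE 0.22, adjusted p = 0.049), each in 2 of 2 comparisons. Xist fell by 8.27 (SE 0.45, adjusted p = 7.9e-09). Among these 4 libraries only MEP1+CMC had high Xist, so the metformin and rapamycin terms also hold the sex-linked difference of that library. Over the list alone, 5 of 13 mitochondrially encoded genes fell, against 0 over all genes. Of 19 Th1 genes none passed (2 rose over the list alone), with a median of -0.15, and camera gave an adjusted p = 0.84, or an adjusted p = 0.96 with an estimated correlation. Camera gave its smallest adjusted p for metformin to the ribosomal protein list (median -0.38, adjusted p = 3.3e-18). The mitochondrially encoded list had a camera adjusted p = 3e-11 and the nuclear oxidative phosphorylation list an adjusted p = 1.9e-09. With an estimated correlation each of these lists had an adjusted p = 0.91. With 1 residual degree of freedom that version could hardly pass, so it decides nothing about these lists. The mitochondrially encoded list failed it at an estimated correlation of -0.077.

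The rapamycin term called 26 genes, of which 7 rose and 19 fell, 7 of them immunoglobulin segments. In models of rapamycin alone, 24 rose and 16 fell without MEP1+CMC, and 12 rose and 5 fell without MEP1+Rapamycin. Genes induced through the T-cell receptor fell, among them Nr4a1 (-1.40, SE 0.22, adjusted p = 0.0075) and the NF-kB inhibitor Tnfaip3 (-1.52, SE 0.24, adjusted p = 0.0075). Odc1 (-1.30, SE 0.21, adjusted p = 0.0095), Angptl2 (-1.60, SE 0.24) and Rgs1 (-1.81, SE 0.28, adjusted p = 0.012) also fell, each in 2 of 2 comparisons. The transcription factor gene Otx1 (chromosome 11, 21994764 to 22002897) rose by 2.18 (SE 0.25, adjusted p = 0.00035), the heat shock gene Hspa1a rose by 1.19 (SE 0.21, adjusted p = 0.012) and Klrg1, a marker of differentiated effector and regulatory cells, rose by 1.47 (SE 0.28, adjusted p = 0.040). Xist fell by 7.51 (SE 0.44, adjusted p = 2.6e-08), although it was lower in 1 of 2 comparisons. Of 19 early TCR response genes 3 fell (8 over the list alone), and of 15 Treg genes 1 rose (4 over the list alone). Camera gave the early TCR response list an adjusted p = 1.2e-16 and the ribosomal protein list an adjusted p = 7.3e-19, but both had an adjusted p = 0.83 with an estimated correlation. A list could hardly pass that version here either.

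The comparison of the combination with No treatment asks how cells after the full CAMCI regimen differed from untreated memory cells. Treg genes were higher. Foxp3 had a log2 ratio of 3.20 (interval 3.06 to 3.34) and Klrg1 2.30 within the Treg list, where 9 of 15 were higher and 1 lower (Il10, -2.34) with a median of 1.14. Bcl2 was higher (1.60), though the anti-apoptotic list had 1 higher and 2 lower of 11 and a median of -0.10, inside the matched random lists and 0.13 with library totals. Also higher were the resting gene Igfbp4 (2.81) and the energy stress genes Txnip (1.41) and Ddit4 (1.48). Immediate TCR target genes were lower, with 5 of 19 passing, none higher and a median of -0.59, led by Egr1 (-2.68) and Nr4a1 (-2.44). The Th1 list had 4 of 19 lower, including Tnf (-1.46) and Ifng (-1.33), with a median of -0.08 that lay inside the matched random lists and was 0.15 with library totals. In the Th17 list Il1r1 was lower (-2.85). Mitochondrially encoded genes had 5 of 13 lower and a median of -0.91, such as mt-Nd1 (-1.26). Of the stress genes of cell dissociation, Atf3 (-2.96) and Junb (-1.35) were lower and Hspa1a (1.08) was higher.

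Macrophage genes were lower in 14 of 17 (Lyz2 -3.87), and erythroid genes were lower in 5 of 10 (Hba-a1 -5.11). B-cell genes were higher in 8 of 14 and lower in 3, with a median of 1.17 that was -0.58 with the stricter filter. Neutrophil genes were higher in 4 of 6, with S100a9 at 5.89 (interval 4.32 to 8.18, 172 against 3 counts), and Xist was lower (-6.23). In all, 1718 genes passed, 1086 higher and 632 lower. With library totals, 1482 were higher and 463 lower.

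The combination was also compared with each single-inhibitor library, all 3 having high Y-linked and low Xist counts. Against MEP1+Metformin, 382 genes passed, 163 higher and 219 lower. Early TCR response genes were lower in 4 of 19, with a median of -0.54, dissociation and heat stress genes had 2 higher and 1 lower of 15 and a median of -0.35, below the matched random lists, the Th1 median was -0.13 (0.00 with the stricter filter), and ribosomal protein genes had a median of 0.25 with none of 36 passing the size rule. Against MEP1+Rapamycin, 813 genes passed, 427 higher and 386 lower. There the Th1 list had 5 of 19 higher and a median of 0.74, B-cell markers had 7 of 14 higher (1.01), plasma-cell markers 5 of 9 (1.02) and CD8 markers 2 of 6 (0.26), and neutrophil markers had 3 higher and 1 lower of 6 (1.10). Ribosomal protein genes had a median of -0.53 and mitochondrially encoded genes a median of -0.51. Over 8620 genes with a mean of at least 10 CPM, the SD of the metformin contrast was 0.290, of the rapamycin contrast 0.294 and of the departure from additivity 0.262. The robust SDs were 0.262, 0.212 and 0.174, and 25, 98 and 57 genes were at least 2-fold.

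Sex-linked genes split the libraries. TMM CPM of Xist was 262 in MEP1+CMC, 43.1 in the naive control and 24.2 in No treatment, against 0.218, 0.486 and 0.323 in MEP1+Metformin, MEP1+Rapamycin and the combination. TMM CPM of Ddx3y was 95.8, 62.0 and 87.0 in those 3 inhibitor libraries, 35.9 in No treatment, 0.307 in MEP1+CMC and 0.377 in the naive control.

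**Figure D3:**
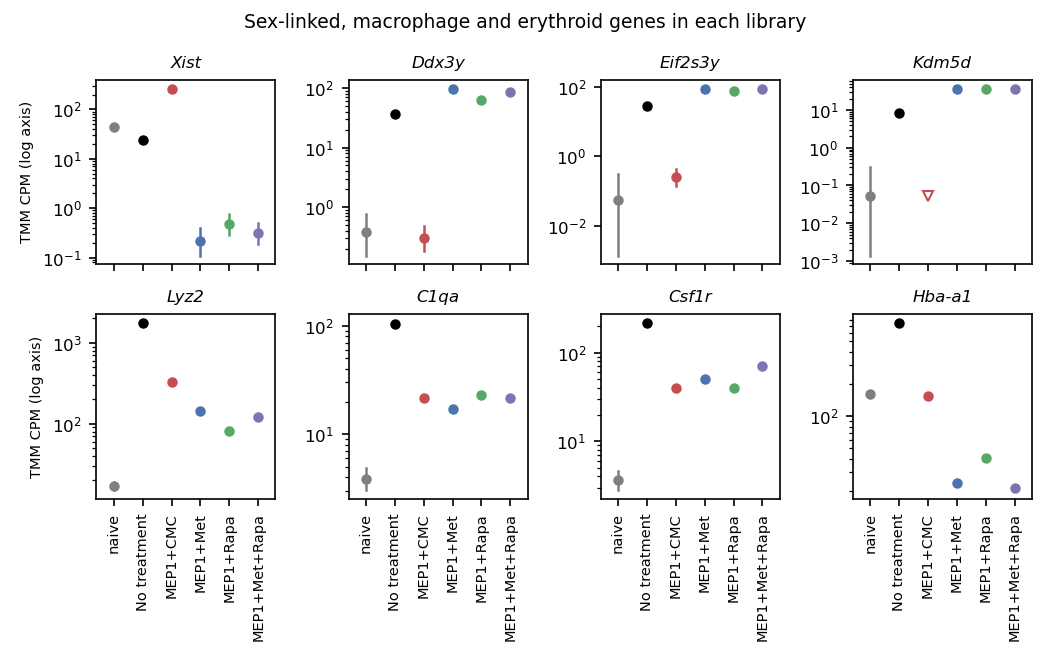
TMM CPM (log axis) of 4 sex-linked, 3 macrophage and 1 erythroid gene in each of the 6 libraries, with bars for the 95% counting interval and an open triangle for a count of 0. Lyz2, C1qa, Csf1r and Hba-a1 were highest in No treatment, and Xist was below 1 in the 3 inhibitor libraries.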

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

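Of the tests in this part, those of T-cell share, sex, handling, CD8 or NK cells, scaling, splits of the libraries, Trav copies and Trav depth were chosen after the results had been seen, while the test of the splenic macrophage genes was written before its values were seen.

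Of the 151 genes that the naming rule takes for the 3 comparisons with MEP1+CMC, 30 reported here passed the size rule in opposite directions for metformin given without and with rapamycin, and 10 for rapamycin given without and with metformin. The differences between the 2 effects were not tested, since each condition had 1 library, and the differences for metformin and for rapamycin rest on the same 4 libraries. For metformin, the genes lower against MEP1+CMC but higher in the combination than in MEP1+Rapamycin included Ccl5 (-1.71 against 1.06), Eomes (-1.97 against 1.64), Nkg7 (-1.93 against 1.18), Tigit (-1.59 against 1.22), Havcr2 (-1.09 against 2.54), Ccr2 (-1.43), Entpd1 (-1.34), Prdm1 (-1.21), Ier3 (-2.08), Rgs16 (-1.67), Adgrg1 (-1.26), Esm1 (-2.38), Spp1 (-1.98), Osr2 (-1.62) and Pak6 (-1.87). Of these, Esm1, Rgs16, Adgrg1, Pak6 and Osr2 were named for low values in MEP1+Rapamycin, the baseline of the second difference, which favours such a direction. The list members Eomes, Tigit and Havcr2 were named for low values there as well. B-cell and plasma-cell genes had the same 2 directions: Blk (-1.41), Cr2 (-1.49), Fcer2a (-2.07), Ms4a1 (-1.31), Ighg1 (-1.80), Jchain (-2.36) and Igha (-8.00, interval -10.28 to -6.44, 3 against 890 counts). So did Ngp (-2.29), Ltf (-3.69, interval -9.09 to -0.99, 1 against 15 counts) and Slc4a1. The last had 0 counts in MEP1+Metformin and was 11.2-fold lower with the floor of 3 counts (-3.48, interval up to -3.12). The reverse directions were found for Grin2b (3.09, interval 1.36 to 5.48, from 3 counts in MEP1+CMC), Kcnj16 (2.90), Lrp2 (1.41), Siglech (1.43) and Cd177. The last had 0 counts in MEP1+CMC (2.63 with the floor of 3 counts, interval from 2.16). Grin2b, Lrp2 and Cd177 were named for high values in MEP1+Rapamycin, which favours the reverse directions.

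For rapamycin, genes lower against MEP1+CMC but higher in the combination than in MEP1+Metformin were Blk (-1.21 against 3.00), Cr2 (-3.05 against 2.59), Igha (-2.55 against 10.89), Slc4a1 (-1.62) and Tsix (-6.07). Genes with the reverse directions were Ly6c2 (1.89 against -1.36), Grin2b (5.40 against -2.28), Kcnj16 (2.85 against -1.09), Lrp2 (3.53 against -1.44) and Siglech (2.17 against -1.81). Tsix and Slc4a1 were named for low values in MEP1+Metformin, the baseline here, and Ly6c2 and Kcnj16 for high values, which favours these directions. The differences for rapamycin were not tested either.

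Trav segments, which belong to endogenous alpha chains or to the transgene, were among the compared genes but were left out by the naming rule. Trav7-4 held 14.0% of Trav counts in No treatment (exact 95% interval 13.3% to 14.9%) and 33.8% in MEP1+CMC (33.0% to 34.6%), above the 1.44% of the naive control. In MEP1+Metformin, MEP1+Rapamycin and the combination it held 1.47%, 1.71% and 2.07%.

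The first pattern weighed was the higher level of macrophage and erythroid transcripts in No treatment. Cells of another type in the sort are a candidate source, since 13 of 13 splenic macrophage genes in no other list (100%) were at least 2-fold higher there than in the mean of the 4 MEP1 libraries, with a median log2 ratio of 1.88. The most abundant were Slc40a1 (208 against 57.5 CPM) and Fcna (145 against 38.1 CPM), 4 of the 13 reached 2 CPM in the naive library, and a clean sort for donor CD4 cells would remove such cells. The 13 genes extend the pattern to further genes of that cell type in the same libraries. They do not show how the transcripts came into the library. A lower share of T cells that raised all other types alike was argued against by the B-cell genes only. The median log2 ratio of MEP1+CMC to No treatment was 0.04 for B-cell genes (-0.57 with the stricter filter) and -2.08 for macrophage genes (-2.10). These were 2.13 apart (95% resampling interval 0.92 to 2.85, over genes taken as independent). Erythroid genes moved with the macrophage genes, as TMM CPM of Hba-a1 was 741 in No treatment and 156 in MEP1+CMC. A lower share of T cells through macrophages and erythroid cells alone therefore stays open. Of 5 splits that set 1 library against the other 4, the real one called 244 genes and the highest other 4, and 5 splits are too few for a share under 0.05.

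The second pattern was the lower level of effector and early TCR response genes in the inhibitor libraries than in MEP1+CMC, where sex-linked genes also differed. Sex of the source mice and the inhibitors cannot be told apart in the step from MEP1+CMC. Within the 3 libraries with Y-linked counts and little Xist, the early TCR response median of the combination was -0.539 against MEP1+Metformin (percentile 0). Its Th1 median was 0.744 against MEP1+Rapamycin (percentile 100) and -0.134 against MEP1+Metformin. The lists thus also differed between libraries alike in sex-linked genes. With 1 library per condition, such differences do not show what made the step from MEP1+CMC. Handling of the tissue stays open for the early TCR response list in the combination, as the dissociation and heat stress list was lower too. The median of that stress list was -0.355 against MEP1+Metformin and -0.452 against MEP1+CMC (percentile 0 in both). In MEP1+Rapamycin against MEP1+CMC, the early TCR response median was -0.93. That of the stress list was -0.05, inside the random lists, with 7 genes above 0 and 8 below, of which 2 passed higher and 1 lower. A median over members that went both ways does not show that handling was alike. CD8 or NK cells in the sort cannot be told apart for the effector genes. Of the 6 medians of their marker lists against MEP1+CMC, 5 were below the random lists, over members that went both ways. Scaling was checked for the combination only, whose Th1 median against MEP1+CMC stayed at most -0.858 under the 2 other scalings. Another scaling shifts all genes alike, so the rank among the random lists could not change. The check therefore shows only that the direction held under these scalings. An effect of the inhibitors on these genes may be another explanation, a hypothesis beside sex, handling, other cells and the single library per condition.

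The third pattern was the less even use of Trav segments in No treatment and MEP1+CMC. Reads shared between near-identical Trav copies would give like shares, but that of Trav7-4 differed by 23.5-fold between libraries. Depth was argued against as well, since after thinning to 2017 Trav counts the lowest effective number of segments in the inhibitor libraries was 2.84 times the highest in No treatment and MEP1+CMC (20.2 against 7.13). Without Trav6d-6 and Trav7-4 the effective number before thinning was 23.9 and 19.2 in No treatment and MEP1+CMC and 24.9 to 27.6 in the inhibitor libraries, so most of the gap rested on these 2 segments, and that of the naive control was 12.2 with them and 19.7 without. Few sorted cells could give the same picture and cannot be told apart from expansion of some clones, since 0 sorted cell numbers were in the sources used here.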

How the results depend on the processing

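Leaving out genes of the X and Y chromosomes was chosen after the values had been seen. All 743 log2 ratios recomputed under the other scalings, filters and trend removals for the 10 higher and 10 lower genes of each pair of libraries kept their direction and their side of the size rule. A filter leaves the ratio of a retained gene unchanged, so only scalings and trend removals could move these values and those of list members. The 10 higher and 10 lower genes had also been chosen for intervals far from no change. For the other named members of the gene lists, 3155 values kept their side of the size rule and 100 came under 2-fold in the same direction (41 with library totals, 32 and 22 with the trend on gene length and on abundance removed, 5 with DESeq2 size factors). With library totals these included Nr4a1 in MEP1+CMC against No treatment (-0.91), Fasl (-0.87) and Isg15 (-0.95) in MEP1+Metformin against MEP1+CMC, and mt-Nd2 (-0.91) in the combination against MEP1+CMC. Of the recomputed list medians, 561 kept their side of the random lists, 8 moved outside them, 4 moved inside and 9 that had been outside changed sign. Another scaling shifts list and random medians alike, so only the stricter filter could move a median across the random lists. Most of the 561 were thus fixed in advance. Of those that had been inside, 53 changed sign as well. Of the recomputed values of named genes in the models, 373 stayed past the threshold and 76 kept the direction but lost it. With 1 library left out, 235 stayed, 39 lost it and 2 reversed.

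The number of genes passing the size rule followed the filter, since a filter sets how many genes are compared. In the order No treatment against naive, MEP1+CMC against No treatment, then MEP1+Metformin, MEP1+Rapamycin and the combination against MEP1+CMC, and the combination against No treatment, it was 4901, 5362, 4440, 7706, 4116 and 5776 without a filter. With the stricter filter it was 1178, 250, 117, 343, 165 and 386. Without genes of the X and Y chromosomes it was 2988, 1442, 700, 1357, 831 and 1669.

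For the models the cause of the changes in number was not tested. In the order transferred against naive, MEP1, metformin and rapamycin, the DESeq2 Wald test called 3614, 1029, 9 and 68 genes, and library totals in edgeR called 2672, 136, 12 and 17. Legacy quasi-likelihood called 2287 genes in the first and 41 for rapamycin, DESeq2 size factors in edgeR called 11 for metformin and 10 for rapamycin, and the stricter filter called 101 in the MEP1 model and 107 for rapamycin. Without a filter, edgeR called 395 in the MEP1 model, 0 for metformin (1031 at an unadjusted p under 0.05) and 0 for rapamycin (846). The model with 1 inhibitor alone called 0 for metformin (855 at an unadjusted p under 0.05) and 13 for rapamycin. Without genes of the X and Y chromosomes, 1242, 249, 17 and 24 were called.

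Leaving out each library in turn gave 693 to 2998 calls for transferred against naive (2998 without No treatment, 746 without MEP1+Metformin, 693 without the combination) and 131 to 323 for the MEP1 model (131 without MEP1+Metformin). With the 1-inhibitor model, it gave 24 to 2602 for metformin (2602 without MEP1+CMC, 555 without MEP1+Rapamycin). For rapamycin it gave 17 to 273 (40 without MEP1+CMC, 273 without MEP1+Metformin, 17 without MEP1+Rapamycin, 101 without the combination). In these fits a lone library was assumed to vary like the others. Without MEP1+CMC, the rapamycin terms of Xist (0.84) and Tsix (6.08) reversed. No paired analysis was possible because each group has 1 sample.

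The 9 medians outside the random lists that reversed were those of nuclear oxidative phosphorylation in MEP1+Rapamycin against MEP1+CMC (0.0072 with DESeq2 size factors, 0.11 with library totals), and, with library totals, energy stress and FOXO (0.053) and interferon response (0.062) in No treatment against naive and CD4 T-cell identity in MEP1+CMC against No treatment (0.056). With the stricter filter, which left fewer members, the NK-cell median in MEP1+Rapamycin against MEP1+CMC was 0.19. The B-cell median was then 0.70 in No treatment against naive, -0.0033 in the combination against MEP1+CMC and -0.58 in the combination against No treatment. The CD8 and neutrophil lists had too few genes for a value with that filter. Over Trbv segments with at least 10 counts in the naive library, the share of Trbv13-1 was 99.2%, 99.2%, 99.0%, 99.2% and 99.1% in No treatment, MEP1+CMC, MEP1+Metformin, MEP1+Rapamycin and the combination. The cause was not tested for the medians that scaling reversed.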

Other observations

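The shares of sex-linked genes, the gene counts after thinning and the splits in this part were chosen after the data had been seen, while the models of naive, metformin and rapamycin libraries set beside the splits were planned. The sex-linked shares and gene counts were not tested. TMM CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in No treatment was 23.8% to 44.0% of the mean of the 3 inhibitor libraries, and that of Xist was 9.22% of MEP1+CMC. Whether libraries hold cells of more than 1 mouse was not given in the sources used here.

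With the 5 rRNA-like loci left out, the other libraries were thinned to the 22111214 counts of the naive control. Genes with a count then numbered 18883 in the naive control, 23563 in No treatment, 24372 in MEP1+CMC, 27845 in MEP1+Metformin, 28751 in MEP1+Rapamycin and 25242 in the combination. The 5 transferred libraries were 24.8% to 52.3% above the naive control.

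Of 6 splits that set 1 library against the other 5, the one with the naive control alone called 1259 genes and the highest other 12. Of the 3 ways to set 2 of the MEP1 libraries against the other 2, metformin called 0 genes by edgeR (855 at an unadjusted p under 0.05, and 9 by the DESeq2 Wald test of the additive model), rapamycin called 13 and the departure from additivity called 1. Both sets of splits are too few for a share under 0.05.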
